A study of Mus musculus with 12 samples.

How the data were processed

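Livers of 12 male ob/ob mice (B6.Cg-Lepob/J, which lack leptin and become obese) were profiled by bulk RNA sequencing. Per the labels' protocols, the mice were 8 weeks old when they were put on chow with a standard protein content (SPD, 25% of energy) or a low protein content (LPD, 5% of energy) for 3 weeks, with free access to food, and 6 separate mice were used per diet. Livers were snap-frozen, RNA was extracted with TRIzol and treated with DNase I, and libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes, TopHat, DESeq2 and the mm10 build were used, without version or role. The counting program, its annotation release, its handling of strand and of reads that map to several genes, and the read length are not given in the sources used here.

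The deposited matrix holds 1 column of expected counts per library for 56980 genes, and the authors had not scaled these estimated counts between libraries. Between 17.1% and 18.9% of the nonzero values of a library were not whole numbers. Totals per library ranged from 19374676 to 23710930 counts. The annotation columns gave symbols for all but 1542 genes, which held 0.214% of the counts. Gene IDs were matched to GENCODE M21 on GRCm38, the assembly of mm10, for coordinates: 52073 were found and 4907 were not, and the found IDs held 99.6% of the counts. A gene length column was deposited too and was used only to match genes by length. KEGG map names from the annotation columns were used for an additional test, chosen after the data were seen.

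Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13768 genes to test. Libraries were scaled by TMM, and the quasi-likelihood F test compared LPD with SPD with no further term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Fold changes are LPD over SPD on the log2 scale. Their standard errors (SE) were derived as the absolute log2 fold change divided by the square root of the F statistic. Expression levels are given in CPM, the usual depth-normalised read count, computed with TMM-scaled totals and printed as mean ± SD over the 6 livers of a diet. Counts are summed over each gene, so no exon, intron or UTR is told apart.

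Gene lists were tested with camera of limma 3.58.1, a two-sided test of whether the genes of a list rank higher or lower than the other genes, on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Lists with at least 3 tested members entered, adjusted over the lists. The 45 lists covered lipid, amino acid, carbohydrate and mitochondrial metabolism, stress responses, ribosomal proteins, bile acids, xenobiotic and glutathione metabolism, growth hormone, sex-biased, insulin and clock genes, autophagy, acute phase and interferon genes, proliferation, zonation, hepatocyte identity, and markers of other cell types. For each list, members past the gene test were counted with the adjustment over all genes and with p-values adjusted over the list alone. The rotation test fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Both fry and camera with an estimated correlation were run as alternatives. An exact two-sided permutation test of the mean log2 CPM of each list over all 924 labelings was added after the data were seen.

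The design, the lists, the tests, the alternatives other than those called added, and the rule for naming genes were fixed before the data were examined. The rule names the 8 higher and 8 lower genes with the largest fold change among called genes with a mean log2 CPM of at least 1 and no overlap between the diets, leaving out predicted genes and pseudogenes. It also names up to 3 called members with the smallest adjusted p of each called list, 1 such member of each other list, and always Fgf21, Asns, Fasn, Acaca, Acly, Scd1, Srebf1, Cpt1a, Pck1, Cps1, Igf1 and Alb. Any other gene named was chosen after its values were seen, as an exception to its list or as an example from a KEGG map. Values of a few genes that the rule names or that were exceptions are not reported here.

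The alternatives were DESeq2 size factors and upper quartile scaling in edgeR, no filter on low counts, a stricter filter (1 CPM in 6 libraries), libraries thinned to equal totals, the Wald test of DESeq2 1.42.0, limma-voom with sample weights, a test for changes beyond 1.5-fold (glmTreat), the replicate number as a block, each library left out in turn, LPD replicate 1 left out or counted as SPD, and the 4 libraries per diet with codes SP1 and LP4 alone. An alternative without LPD replicates 2 and 5 was added after the data were seen. Libraries were compared by principal components and by Pearson correlation of log2 CPM. The gene test was repeated on 100 splits of the 12 libraries into 6 and 6, the real one included. A search for duplicated libraries compared counts of each pair gene by gene with sampling noise.

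Calls were tested on simulated data of 13768 genes with the measured means and dispersions, of which 200 were changed. The 200 were drawn only from genes above a set mean count, so recovery of genes with lower counts was not measured. The test recovered 67.2% of genes changed 1.5-fold, 95.5% of those changed 2-fold and all of those changed 4-fold, and 3.85% of called genes had not been changed. In the livers 39.9% of tested genes were called, a far larger share than was changed here. The adjustment depends on that share, so the recovery need not hold for the real comparison. With no change simulated, 1 gene and no list were called. The simulated genes were drawn independently of one another, so this does not measure false list calls where the genes of a list are correlated. Tables were read with the data.table package (version 1.17.8). No library or count column was left out of the comparison.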

Results

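RNA of 12 livers from obese ob/ob males was sequenced, 6 from mice on the standard protein diet (SPD) and 6 from mice on the low protein diet (LPD). Total counts per library ranged from 19374676 to 23710930 in SPD livers and from 19404340 to 23681408 in LPD livers, and 18094 to 18998 genes had a count. The 10 genes with most counts took 22.1 ± 0.961% of the counts of SPD livers and 16.1 ± 0.747% of those of LPD livers (mean ± SD, n = 6). Transcripts of the mitochondrial genome took 6.16 ± 0.430% and 5.21 ± 0.287%. No pair of libraries had counts as alike as sampling noise would give.

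The first principal component, with 47.1% of the variance, separated the diets. All SPD livers lay between -32.1 and -24.7, and LPD livers between 15.3 and 48.7. LPD replicates 2 and 5 stood apart from the other LPD livers on the first component, at 48.7 and 44.6, and on the second, with 10.2% of the variance, at 20.3 and 22.3. Each library correlated more closely with its own diet (mean Pearson r over genes 0.982 to 0.987) than with the other (0.958 to 0.975). For LPD replicate 1, 2 labels conflict with its title and library code: its treatment and description name the standard protein content. Its mean r was 0.984 with the other LPD livers and 0.975 with the SPD livers, and it was kept in LPD. Library codes begin SP1 or SP2 in SPD and LP4 or LP5 in LPD, with 4 and 2 libraries each. The labels name no batch. No code occurs in both diets, so if the codes stand for batches, these and the diet cannot be told apart. SPD livers of both codes lay together on the first component, but this does not bear on a difference between SP and LP codes.

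**Figure D1:**
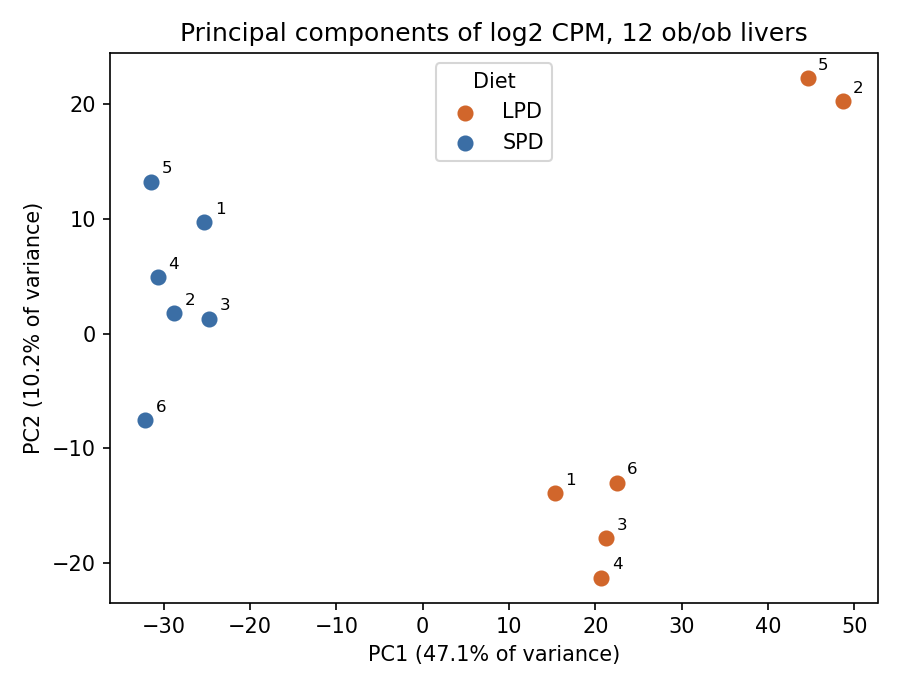
Principal components of log2 CPM over all tested genes, with 1 point per liver, numbered by replicate and coloured by diet; the axes give the component scores and the share of variance (47.1% and 10.2%). SPD livers lie between -32.1 and -24.7 on the first component and LPD livers between 15.3 and 48.7, with LPD replicates 2 and 5 highest on both components.

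The comparison of LPD with SPD asks how protein restriction changed liver metabolism in these steatosis-prone mice. In LPD livers, 16 of 20 mRNAs of fatty acid synthesis and 24 of 25 of cholesterol synthesis and uptake fell, among them Scd1, Fasn, Elovl6 and Dhcr7. Of 37 genes of the ATF4 and amino acid response, 21 rose, among them Fgf21, Trib3, Chac1 and Asns, and 2 fell. ATF4 is a transcription factor that answers amino acid shortage. Rises were made by 12 of 22 pericentral genes, among them Cyp2e1, and by 53 of 57 ribosomal protein, 16 of 23 ER chaperone and 9 of 16 IGF axis mRNAs. Falls were made by 26 of 27 cell cycle, 21 of 28 glutathione and 13 of 25 glycolysis mRNAs, and by 8 of 16 lipid-associated macrophage and 13 of 24 stellate cell markers, which were lowest in LPD replicates 2 and 5. Each of these lists was called by camera, and none of the calls held with an estimated correlation.

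Of 13768 genes tested, 2850 were higher and 2646 lower in LPD livers, and 8272 did not pass. At least 2-fold changes were made by 190 of the higher and 469 of the lower genes. The diets did not overlap for 1394 of the higher and 1333 of the lower genes. Of all tested genes 19.9% did not overlap, against 0.216% expected by chance. The median log2 fold change of all tested genes was near 0. Below, a value behind a gene symbol is its log2 fold change (LPD over SPD) ± SE with n = 6 per diet, and CPM are means, ± SD where given, in SPD and then LPD livers. The genes named by the rule did not overlap between diets, with all 6 livers of 1 diet above all 6 of the other, except Nfil3, Col5a2, Ighm, Rgs5, Cd14, mt-Nd2, Col3a1, mt-Co1, Mmp9, Cpt1a, Alb, Srebf1, Cps1 and Pck1. Of 45 gene lists 44 could be tested and 22 were called by camera, 12 up and 10 down. With an estimated correlation camera called 0 lists, and 5 had an unadjusted p under 0.05. By fry 27 lists passed.

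De novo lipogenesis mRNAs fell together: 16 of 20 fell, 1 rose and 3 did not pass, with a median of -1.29 (adjusted p = 2.30e-12, and adjusted p = 0.283 with an estimated correlation). Adjusted over the list alone, 18 fell and 1 rose. Scd1, a stearoyl-CoA desaturase (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879, minus strand, GRCm38), fell 6.59-fold from 43382 ± 6847 to 6583 ± 753 CPM (-2.72 ± 0.12, adjusted p = 2.98e-09). Fasn, fatty acid synthase (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547, minus strand), fell 6.74-fold from 1799 ± 539 to 267 ± 65.6 CPM (-2.75 ± 0.21, adjusted p = 2.25e-07). ATP citrate lyase Acly went from 871 ± 297 to 171 ± 16.8 CPM (-2.35 ± 0.19) and acetyl-CoA carboxylase Acaca from 726 ± 195 to 165 ± 28.7 CPM (-2.14 ± 0.17). Larger falls were made by the desaturase Scd2 (-3.51 ± 0.21, 205 to 18.03 CPM), the elongase Elovl6 (-3.28 ± 0.23, 933 to 95.7 CPM) and Pnpla3 (-3.34 ± 0.32, 4.76 to 0.465 CPM). Srebf1, which encodes the lipogenic transcription factor SREBP-1, did not pass (-0.074 ± 0.11, adjusted p = 0.646, 158 ± 37.8 to 149.8 ± 8.74 CPM), and its estimate changed sign without SPD replicate 3 (0.071). Mcat and Thrsp did not pass either, and Mlxipl, which encodes ChREBP, was the 1 member that rose (0.23 ± 0.084, adjusted p = 0.0366); these 3 were chosen after their values were seen. The Mlxipl rise was not called by limma-voom, with LPD replicate 1 counted as SPD, in the SP1 and LP4 libraries alone, without LPD replicates 2 and 5, or without any 1 of SPD replicates 1, 3, 4 and 6 and LPD replicates 2, 4 and 5.

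Cholesterol synthesis and uptake mRNAs fell in 24 of 25 cases, 24 adjusted over the list alone, and Ebp, chosen after its value was seen, did not pass. The median was -1.47 (adjusted p = 6.00e-17, and adjusted p = 0.306 with an estimated correlation). Dhcr7, the last reductase of the pathway, fell from 131 ± 25.6 to 33.7 ± 4.28 CPM (-1.96 ± 0.12, adjusted p = 5.67e-08). Insig1 fell from 354 to 116 CPM (-1.61 ± 0.11) and Acat2 from 238 to 87.6 CPM (-1.44 ± 0.11). Both lipid synthesis lists fell in the livers without LPD replicates 2 and 5 as well, with medians of -1.24 and -1.36.

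**Figure D2:**
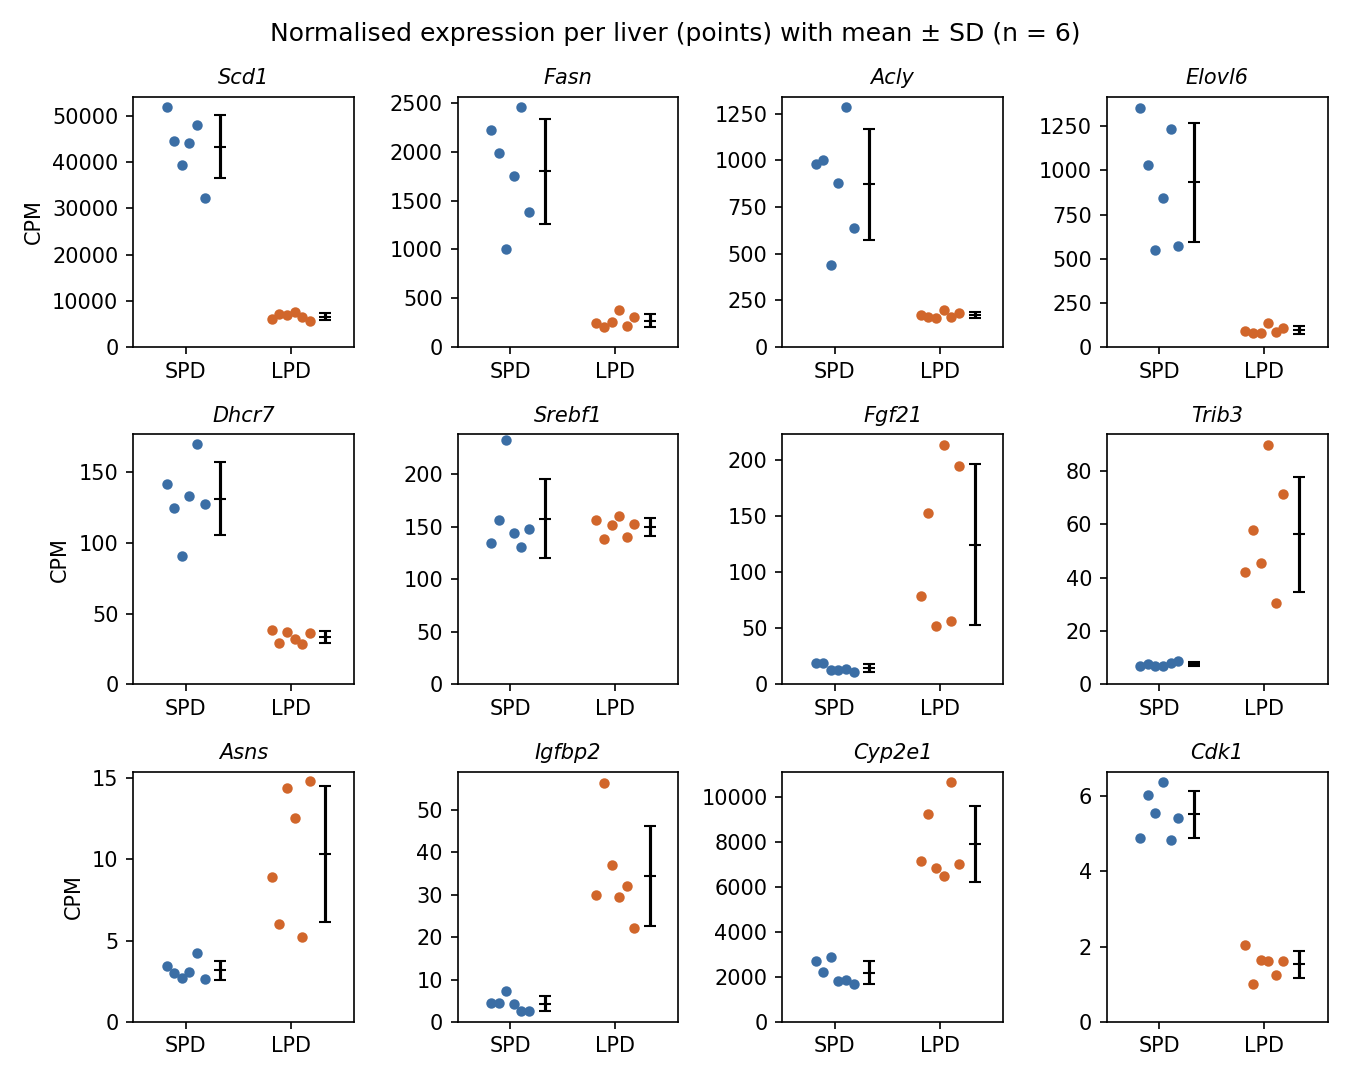
CPM of 12 named genes per liver, with 1 point per liver (6 SPD, 6 LPD) and the mean ± SD of each diet. Scd1 fell from 43382 to 6583 CPM and Fasn from 1799 to 267 CPM, Fgf21 rose from 14.8 to 125 CPM and Cyp2e1 rose too, while the livers of both diets overlapped for Srebf1.

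Genes of the ATF4 and amino acid response rose in 21 of 37 cases, 2 fell and 14 did not pass, with a median of 0.50 (adjusted p = 5.47e-06, and adjusted p = 0.435 with an estimated correlation). Adjusted over the list alone, 23 rose and 3 fell. Fgf21, a hormone secreted by the liver (ENSMUSG00000030827, chromosome 7, 45613886 to 45615490, minus strand), rose 8.45-fold from 14.8 ± 3.47 to 125 ± 71.6 CPM (3.08 ± 0.34, adjusted p = 8.02e-06). The pseudokinase Trib3 rose 7.47-fold from 7.52 ± 0.760 to 56.1 ± 21.5 CPM (2.90 ± 0.22, adjusted p = 2.14e-07) and Chac1, which degrades glutathione, 10.5-fold (3.39 ± 0.33, 2.40 to 25.1 CPM). Asparagine synthetase Asns rose from 3.18 ± 0.584 to 10.3 ± 4.19 CPM (1.70 ± 0.25, adjusted p = 8.19e-05). Atf5 (1.33 ± 0.071), Herpud1 (1.20 ± 0.056), the transporter chain Slc3a2 (0.96 ± 0.077) and the serine synthesis enzyme Psat1 (1.41 ± 0.16) rose as well. The cystine transporter Slc7a11 (-1.38 ± 0.42) and the proline synthesis enzyme Aldh18a1 (-0.91 ± 0.23) fell, and both were chosen after their values were seen. LPD replicate 5 had the lowest score of the LPD livers, 0.167 above the SPD mean against 0.584 to 0.951 in the others. It was the lowest LPD liver for Chac1 (8.52 CPM), Trib3 (30.5 CPM) and Asns (5.21 CPM) too. Without LPD replicates 2 and 5 the median of the list was 0.54.

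ER chaperones and genes of the unfolded protein response rose in 16 of 23 cases and none fell by edgeR (7 did not pass, and adjusted over the list alone 18 rose and 1 fell), with a median of 0.45 (adjusted p = 1.80e-05, and adjusted p = 0.536 with an estimated correlation). Xbp1 rose from 114 to 179.6 CPM (0.65 ± 0.077), the lectin chaperone Calr from 435 to 699 CPM (0.68 ± 0.099), and Dnajc3 by 0.54 ± 0.069. LPD replicate 2 had the highest Calr level, 845 CPM, and the median of the list was 0.29 without LPD replicates 2 and 5.

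Amino acid catabolism, the pathway that the series title bears on, moved both ways: 20 of 58 rose, 15 fell and 23 did not pass, with 22 and 15 adjusted over the list alone. Its median was 0.082 (adjusted p = 0.346, not called). Acmsd, of the tryptophan pathway, fell most firmly (-2.09 ± 0.18, 13.3 to 3.12 CPM). The list's mean changed sign without LPD replicates 2 and 5 (-0.013), where the median was 0.011. Of 10 urea cycle and ammonia genes, 3 rose and 2 fell, also adjusted over the list alone, and 5 did not pass. The median was -0.057, the mean -0.024 and the direction of the test up (adjusted p = 0.944), and the mean was positive without SPD replicate 1 (0.0066), SPD replicate 3 (0.016), LPD replicate 1 (0.0092) or LPD replicate 4 (0.0048). Glul, glutamine synthetase, rose (0.59 ± 0.093, adjusted p = 0.000170) with Slc25a13 (0.26 ± 0.054) and Nags (0.41 ± 0.099), whereas Ass1 (-0.68 ± 0.13) and Arg1 (-0.35 ± 0.065) fell; all but Glul were chosen after their values were seen. Cps1, the first enzyme of the cycle, did not pass (0.083 ± 0.14, adjusted p = 0.664, 1984 ± 401 to 2102 ± 384 CPM). In the SP1 and LP4 libraries alone the Cps1 estimate was -0.11.

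Serine, glycine and one-carbon genes went both ways, with 7 of 25 risen, 5 fallen and 13 not past, the same counts adjusted over the list alone. Their median was -0.012 (-0.075 without LPD replicates 2 and 5), the mean 0.091 and the test's direction up (adjusted p = 0.883, not called). Psat1 rose from 6.39 to 16.9 CPM, while Aldh1l1 (-0.53 ± 0.082), Gnmt (-0.51 ± 0.15), Gldc (-0.25 ± 0.073) and Mthfd1l (-0.29 ± 0.11) were among those that fell, these 4 chosen after their values were seen. Amino acid transporters rose in 6 and fell in 9 of 26 cases, with 6 and 9 adjusted over the list alone and 11 not past. Slc3a2 had the smallest adjusted p. The median of the transporters was -0.069 (0.0085 without LPD replicates 2 and 5), the mean 0.016 and the test's direction down (adjusted p = 0.940, not called), and the mean was -0.0046 without LPD replicate 6.

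Fatty acid oxidation and ketogenesis mRNAs rose modestly: 12 of 24 rose, Ehhadh (-0.57 ± 0.12, chosen after its value was seen) fell and 11 did not pass, with 13 and 1 adjusted over the list alone. The median was 0.19 (adjusted p = 0.00134, and adjusted p = 0.608 with an estimated correlation), and 0.095 without LPD replicates 2 and 5. Acaa1a (0.46 ± 0.056), Eci2 (0.48 ± 0.064) and the ketone body enzyme Bdh1 (0.34 ± 0.051) rose. Cpt1a, which admits long-chain fatty acids to mitochondria, rose by 0.19 ± 0.057 (adjusted p = 0.0132), a call lost with LPD replicate 1 counted as SPD (adjusted p = 0.157) and in the SP1 and LP4 libraries alone (0.130), the highest values over its alternatives. PPAR alpha targets were not called (adjusted p = 0.159, median 0.21): 10 of 24 rose, 5 fell and 9 did not pass, also adjusted over the list alone for both directions. The median was 0.075, with 7 risen, without LPD replicates 2 and 5. Cyp4a32 rose (0.85 ± 0.086), though reads shared among Cyp4a paralogs leave the member uncertain, while Pdk4 (-0.85 ± 0.19), Plin2 (-0.66 ± 0.11), Ehhadh, Ucp2 (-0.54 ± 0.085) and Fabp1 (-0.35 ± 0.11) fell, chosen after their values were seen.

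Lipid droplet and triglyceride storage genes were not called (adjusted p = 0.206, median -0.079), although an exact permutation test of their mean passed (adjusted p = 0.0106). Of 28 members 6 rose, 11 fell and 11 did not pass, with the same numbers risen and fallen adjusted over the list alone. Plin5, a coat protein of droplets next to mitochondria, rose from 51.4 to 100.4 CPM (0.97 ± 0.10), and hormone-sensitive lipase Lipe fell (-0.64 ± 0.076). VLDL and apolipoprotein genes were not called either (adjusted p = 0.241, median 0.17, and 0.097 without LPD replicates 2 and 5), with 10 of 20 risen and 5 fallen, also adjusted over the list alone, and 5 not past. Apoc2 fell (-1.06 ± 0.076), with Pltp (-1.0 ± 0.088), Apoa4 (-0.61 ± 0.13), Apoc3 (-0.53 ± 0.095) and Mttp (-0.27 ± 0.070), the last 4 chosen after their values were seen.

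Glycolysis and fructolysis mRNAs fell in 13 of 25 cases, with 2 risen and 10 not past (13 and 3 adjusted over the list alone). Their median was -0.33 (adjusted p = 0.00187, and adjusted p = 0.435 with an estimated correlation). Gapdh fell from 2961 to 1546 CPM (-0.94 ± 0.084), Pgam1 (-0.56 ± 0.056) and Eno1 (-0.70 ± 0.089). The glucose transporter Slc2a2 (0.16 ± 0.061), chosen after its value was seen, was among those that rose. Gluconeogenesis was not called (adjusted p = 0.195, median 0.17), although fry passed (adjusted p = 0.0371), with 4 of 14 risen, Got1 fallen (-0.78 ± 0.23) and 9 not past, the same numbers risen and fallen adjusted over the list alone. Foxo1 rose (0.56 ± 0.083), with Gpd1 (0.41 ± 0.094), Crtc2 (0.31 ± 0.090) and Creb1 (0.25 ± 0.092), which like Got1 were chosen after their values were seen. Pck1, its rate-setting enzyme, did not pass (0.033 ± 0.12, adjusted p = 0.858, 2239 to 2290.1 CPM), and its estimate was negative without SPD replicate 5 (-0.029), LPD replicate 4 (-0.031) or LPD replicate 6 (-0.030).

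TCA cycle mRNAs were not called (adjusted p = 0.0870, median -0.058), although 8 of 21 fell, among them fumarase Fh1 (-0.43 ± 0.059), Idh3a rose (0.25 ± 0.071, chosen after its value was seen) and 12 did not pass. Adjusted over the list alone, 9 fell and 1 rose. The list was called down without SPD replicate 6 (adjusted p = 0.0396), LPD replicate 2 (0.0355) or LPD replicate 5 (0.0322), without both of the latter (0.00448, median -0.14) and in the SP1 and LP4 libraries alone (0.0254). The fixed list of nuclear oxidative phosphorylation genes was not called (adjusted p = 0.296, median -0.050): 2 of 39 rose, 5 fell and 32 did not pass. Adjusted over the list alone, edgeR called 0 of them, whereas 2 rose and 8 fell at an unadjusted p under 0.05, and DESeq2 called 2 risen and 6 fallen, limma-voom 2 and 8, over all genes. Without LPD replicates 2 and 5 the list was called down (adjusted p = 0.00671, median -0.11), as was the wider KEGG map of oxidative phosphorylation with all livers (adjusted p = 0.0369, and 0.814 with an estimated correlation), where 8 of 118 genes rose and 25 fell. Ndufb10 (0.27 ± 0.076) and Ndufs7 (0.24 ± 0.077) rose, and Ndufb8 (-0.22 ± 0.077), Ndufa10 (-0.19 ± 0.068), Uqcrfs1 (-0.18 ± 0.056) and Ndufs4 (-0.14 ± 0.049) were among those that fell, all but Ndufb10 chosen after their values were seen. The Ndufb10 call was lost in the SP1 and LP4 libraries alone (adjusted p = 0.0644) and without LPD replicates 2 and 5 (0.0590). Messages encoded by the mitochondrial genome fell in 4 of 13 cases, also adjusted over the list alone, and 9 did not pass, with a median of -0.21 (adjusted p = 0.0224, and adjusted p = 0.608 with an estimated correlation). mt-Atp6 (-0.44 ± 0.075), mt-Nd2 (-0.41 ± 0.088), mt-Co1 (-0.35 ± 0.090) and mt-Cytb (-0.26 ± 0.083, chosen after its value was seen) fell, and nuclear copies can share their reads. Without SPD replicate 2 the list missed the threshold (adjusted p = 0.0526), as it did with LPD replicate 1 counted as SPD (0.0932) and by exact permutation (adjusted p = 0.0513). With LPD replicate 1 counted as SPD, mt-Co1 was no longer called (adjusted p = 0.0828).

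Cytosolic ribosomal protein mRNAs rose in 53 of 57 cases, also adjusted over the list alone, and Rps2, Rps13, Rps29 and Rpl38, chosen after their values were seen, did not pass. The rise was small, with a median of 0.27 (adjusted p = 2.72e-14, and adjusted p = 0.435 with an estimated correlation). Rpl3 rose by 0.53 ± 0.064, Rpl30 by 0.46 ± 0.065 and Rps9 by 0.41 ± 0.056. LPD replicate 6 was the lowest LPD liver for this list, at 0.146 above the SPD mean, against 0.280 to 0.331 in the other LPD livers. Without LPD replicates 2 and 5 the median was 0.26.

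Xenobiotic metabolism genes rose in 18 of 30 cases, 4 fell and 8 did not pass, with 19 and 4 adjusted over the list alone. The median was 0.52 (adjusted p = 1.09e-06, and adjusted p = 0.435 with an estimated correlation). Cyp2c54 rose from 19.2 to 94.3 CPM (2.30 ± 0.17), Cyp2c50 from 199 to 644 CPM (1.69 ± 0.12) and Ugt1a1 by 1.23 ± 0.098, although reads shared among Cyp2c and Ugt1a members leave their split uncertain. Cyp2a4 (-1.10 ± 0.24), Ces2c (-0.87 ± 0.11), Ugt2b1 (-0.23 ± 0.075) and Ephx1 (-0.18 ± 0.068) fell, chosen after their values were seen. The KEGG map of xenobiotic metabolism by cytochrome P450 was called down (10 of 56 rose and 24 fell, adjusted p = 0.0486, and 0.674 with an estimated correlation). That map holds other genes too, among them Gsta4 of the glutathione list, so the direction of the fixed list does not extend to it. Pericentral hepatocyte genes, those most expressed around central veins, rose in 12 of 22 cases and none fell by edgeR (10 did not pass, and adjusted over the list alone 13 rose), with a median of 0.47 (adjusted p = 5.78e-05, and adjusted p = 0.510 with an estimated correlation). Cyp2e1 rose 3.61-fold from 2194 ± 510.0 to 7915 ± 1673 CPM (1.85 ± 0.16, adjusted p = 6.89e-07). Cyp1a2 rose from 66.8 to 178 CPM (1.41 ± 0.12) and Cyp2c37 from 66.5 to 336 CPM (2.34 ± 0.21). Cyp2e1, Cyp1a2 and Cyp2c37 are members of the xenobiotic list too, so the rises of these lists are not separate results. Periportal genes were not called (adjusted p = 0.152, median -0.14), with 2 of 20 risen and 8 fallen, also adjusted over the list alone, and 10 not past. The periportal list was called down in the SP1 and LP4 libraries alone (adjusted p = 0.0254) and passed fry (adjusted p = 0.0325). Igfals (1.11 ± 0.14) and Apof (0.22 ± 0.068, chosen after its value was seen) rose and Aldh1b1 fell (-1.01 ± 0.10). Without LPD replicates 2 and 5 the medians were 0.45 for xenobiotic and 0.37 for pericentral genes. Whether the change differed between pericentral and periportal genes was not tested.

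Bile acid synthesis and transport genes rose in 17 of 24 cases, 2 fell and 5 did not pass, with 18 and 2 adjusted over the list alone. Their median was 0.36 (adjusted p = 6.79e-05, and adjusted p = 0.435 with an estimated correlation). The oxysterol hydroxylase Cyp39a1 rose from 36.8 to 109 CPM (1.57 ± 0.080), and the nuclear receptor genes Nr1h4 (0.47 ± 0.068) and Nr5a2 (0.35 ± 0.044) rose less. Cyp8b1, of cholic acid synthesis, fell (-1.28 ± 0.32), as did the exporter Abcc2 (-0.33 ± 0.062), both chosen after their values were seen. NRF2 and glutathione genes fell in 21 of 28 cases, also adjusted over the list alone, Gsta3 rose (0.36 ± 0.072, chosen after its value was seen) and 6 did not pass. Their median was -0.59 (adjusted p = 1.17e-08, and adjusted p = 0.283 with an estimated correlation). Gsta4 fell from 69.1 to 24.1 CPM (-1.52 ± 0.11), Gsta2 (-1.61 ± 0.14) and Pgd, which makes NADPH in the pentose phosphate pathway, from 228 to 70.9 CPM (-1.68 ± 0.13). Near-identical Gsta genes can share reads. Without LPD replicates 2 and 5 the medians were 0.28 for bile acid and -0.50 for glutathione genes.

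**Figure D3:**
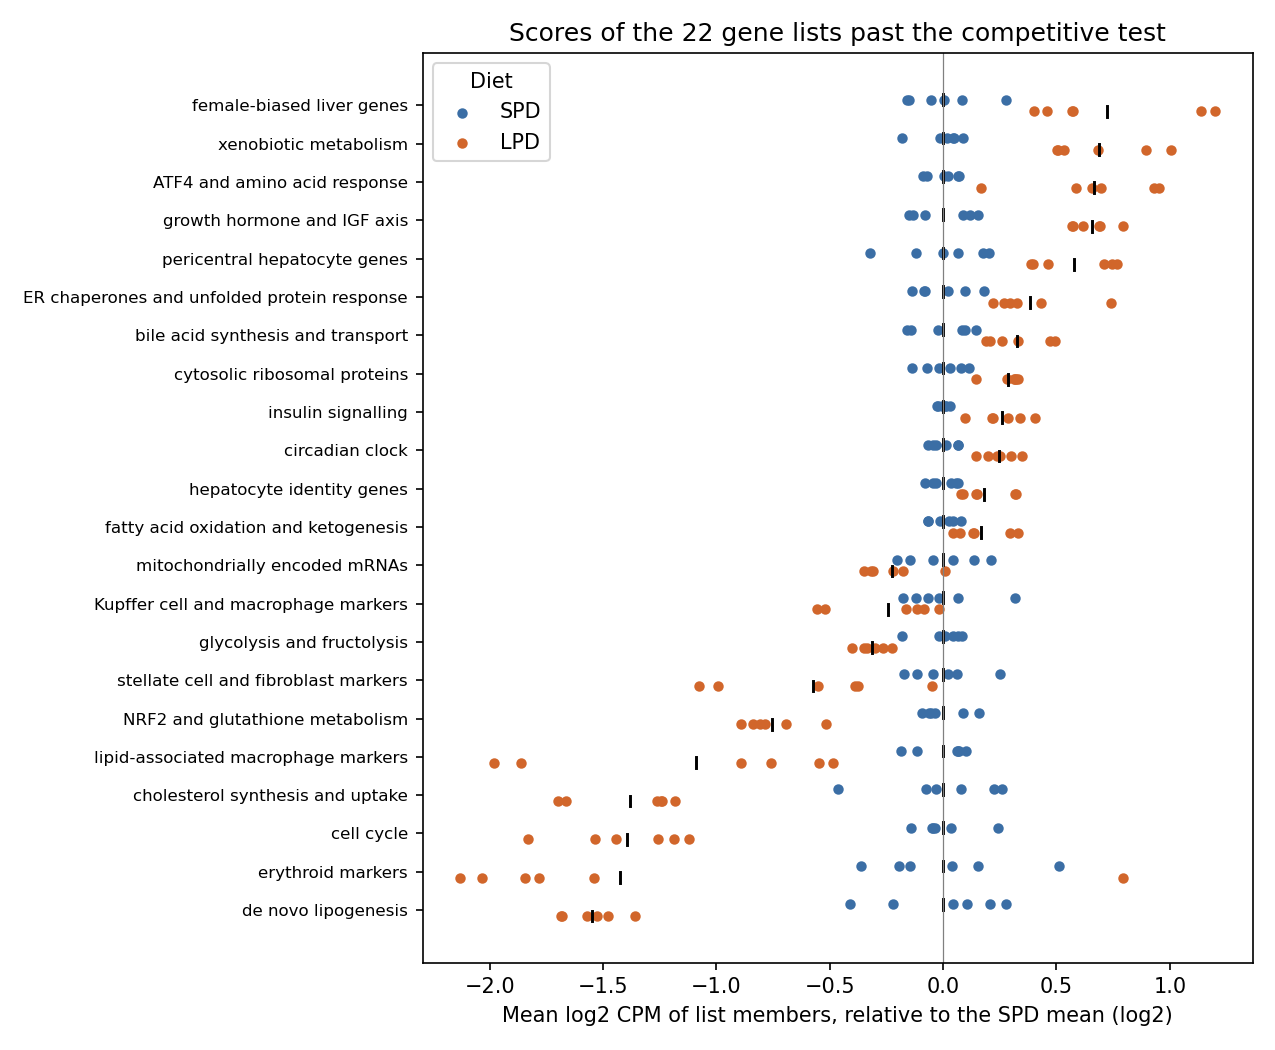
Mean log2 CPM of the members of each of the 22 called lists per liver, relative to the SPD mean (horizontal axis, log2), with 1 point per liver, coloured by diet, and a black tick at each diet mean. LPD replicates 2 and 5 lie lowest for lipid-associated macrophage markers, at -1.86 and -1.98, and all LPD livers lie below all SPD livers for cholesterol synthesis and cell cycle genes.

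Genes of the growth hormone and IGF axis rose in 9 of 16 cases and none fell by edgeR (7 did not pass, and adjusted over the list alone 10 rose), with a median of 0.58 (adjusted p = 0.00187, and adjusted p = 0.283 with an estimated correlation). Igfbp2, an IGF-binding protein, rose 8.06-fold from 4.26 ± 1.75 to 34.5 ± 11.8 CPM (3.01 ± 0.25, adjusted p = 5.03e-07). Igfals rose by 1.11 ± 0.14, Igfbp4 by 0.52 ± 0.060 and Igf1 from 216 ± 44.4 to 337 ± 38.6 CPM (0.64 ± 0.12, adjusted p = 0.000689). Female-biased liver genes rose in 15 of 27 cases, 3 fell and 9 did not pass, also adjusted over the list alone, with a median of 0.41 (adjusted p = 0.00181, and adjusted p = 0.510 with an estimated correlation). Cyp2b10 (1.51 ± 0.12) and Fmo2 (1.04 ± 0.11) rose, while Cyp2a4 (-1.10 ± 0.24), Prom1 (-0.87 ± 0.25) and Rtn4 (-0.44 ± 0.068) fell, these 3 chosen after their values were seen. Some female-biased genes stand in other lists too, such as Cyp2b10 and Cyp2a4 in the xenobiotic list and Cyp39a1 in the bile acid list. Male-biased genes were not called (adjusted p = 0.400), with 4 of 22 risen, 5 fallen, also adjusted over the list alone, and 13 not past. Their median was -0.069 (-0.12 without LPD replicates 2 and 5), the mean 0.0085 and the test's direction down. C6 (-1.17 ± 0.11) and Selenbp2 (-2.41 ± 0.23) fell with Cyp2u1, Gstp1 and Ugt2b1, and Elovl3 (2.48 ± 0.31) rose with Mup1, Mup7 and Ugt2b38, all but C6 chosen after their values were seen. Without LPD replicates 2 and 5 the medians of the growth hormone and female-biased lists were 0.59 and 0.24. LPD replicate 2 lay at 0.444 for male-biased genes, above -0.274 to -0.093 in the other LPD livers, and without it the mean of the list was -0.138.

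Insulin signalling genes rose in 7 of 16 cases, also adjusted over the list alone, none fell by edgeR and 9 did not pass, with a median of 0.15 (adjusted p = 0.04997, and adjusted p = 0.435 with an estimated correlation). The adjusted p lay at the threshold and was above it in 10 alternatives (0.0503 to 0.0737). Among these were the fits without SPD replicates 1 (0.0527), 2 (0.0534), 3 (0.0641), 4 (0.0538) or 5 (0.0521) or LPD replicate 4 (0.0737). Tsc22d3, a FOXO and glucocorticoid target, rose by 0.89 ± 0.13, Pik3r1 by 0.59 ± 0.082 and Foxo1 by 0.56 ± 0.083. Clock genes rose in 9 of 20 cases, Wee1 fell (-0.22 ± 0.062, chosen after its value was seen) and 10 did not pass, the same numbers risen and fallen adjusted over the list alone. Their median was 0.21 (adjusted p = 0.0293, and adjusted p = 0.435 with an estimated correlation). Hlf (0.64 ± 0.071), Usp2 (0.63 ± 0.084) and Nfil3 (1.17 ± 0.21) rose, and the hour of harvest is not given in the sources used here. Hepatocyte identity genes rose in 11 of 23 cases, 2 fell and 10 did not pass, with 12 and 2 adjusted over the list alone. The median was 0.19 (adjusted p = 0.00701, and adjusted p = 0.608 with an estimated correlation), and the call was lost without LPD replicates 2 and 5 (adjusted p = 0.0535). Rbp4 (0.93 ± 0.069) and Ahsg (0.84 ± 0.083) rose, and complement C9 (-1.91 ± 0.15) and Trf (-0.61 ± 0.076, chosen after its value was seen) fell. Albumin mRNA did not pass (-0.20 ± 0.11, adjusted p = 0.174, 65535 to 57232 CPM). It did pass, lower in LPD, without LPD replicate 5 (-0.27, adjusted p = 0.0451), without LPD replicates 2 and 5 (-0.34, adjusted p = 0.00522) and with limma-voom (-0.26, adjusted p = 0.0285), and its adjusted p reached 0.616 with LPD replicate 1 counted as SPD.

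Cell cycle genes fell in 26 of 27 cases, also adjusted over the list alone, and Tk1, chosen after its value was seen, did not pass. Their median was -1.55 (adjusted p = 2.72e-14, and adjusted p = 0.283 with an estimated correlation). Levels were low: Cdk1 fell from 5.52 ± 0.615 to 1.54 ± 0.359 CPM (-1.84 ± 0.15, adjusted p = 5.39e-07). E2f1 (-1.55 ± 0.12) and Mcm2 (-1.30 ± 0.13) fell too. All 6 LPD livers lay below all 6 SPD livers for the list, as they did for lipid-associated macrophage markers, and bulk RNA assigns neither to a cell type. The median was -1.34 without LPD replicates 2 and 5. Genes of p53 and growth arrest were not called (adjusted p = 0.128, median -0.30, and -0.19 without LPD replicates 2 and 5): 3 of 16 rose, 8 fell, also adjusted over the list alone, and 5 did not pass. Gadd45a rose from 5.67 to 37.7 CPM (2.73 ± 0.19), with Cdkn1a (1.03 ± 0.18) and Trp53inp1 (0.90 ± 0.15), the latter pair chosen after their values were seen.

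Autophagy and lysosome genes were not called (adjusted p = 0.277, median -0.048, and -0.0012 without LPD replicates 2 and 5), with 5 of 25 risen and 8 fallen, also adjusted over the list alone, and 12 not past. Ctsd fell (-0.77 ± 0.062). Acute phase genes were not called (adjusted p = 0.103, median 0.16), with 9 of 25 risen and 5 fallen, also adjusted over the list alone, and 11 not past. Apcs, serum amyloid P, rose from 153 to 562 CPM (1.88 ± 0.12), and Orm1 (-0.93 ± 0.14), Il1rn (-0.73 ± 0.14), Orm2 (-0.66 ± 0.22), Steap4 (-0.40 ± 0.13) and Cp (-0.35 ± 0.098) fell, chosen after their values were seen. This list was called up without SPD replicate 6 (adjusted p = 0.0173) or LPD replicate 4 (0.0430) and with no low-count filter (0.0251). Interferon response genes were not called (adjusted p = 0.940, median 0.020, and 0.15 without LPD replicates 2 and 5), with 4 of 24 risen, 4 fallen and 16 not past, and 2 and 3 adjusted over the list alone. Bst2 fell (-0.42 ± 0.067). SPD replicate 6 had the highest interferon score of the SPD livers, 0.664 above their mean, and without LPD replicate 6 the mean change of the list was -0.021. Immediate early and heat shock genes were not called (adjusted p = 0.871, median 0.025, and 0.052 without LPD replicates 2 and 5), with 4 of 19 risen and 2 fallen, also adjusted over the list alone, and 13 not past. Ier2 rose (0.59 ± 0.090).

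Lipid-associated macrophage markers fell in 8 of 16 cases, 10 adjusted over the list alone, none rose by edgeR and 8 did not pass. Their median was -0.76 (adjusted p = 6.86e-05, and adjusted p = 0.536 with an estimated correlation), and -0.43 without LPD replicates 2 and 5. Fabp5, a fatty acid-binding protein, fell 10.8-fold from 79.9 ± 17.5 to 7.38 ± 3.21 CPM (-3.43 ± 0.25, adjusted p = 1.48e-07). Anxa5 fell from 485 to 196 CPM (-1.31 ± 0.15), Cd9 (-1.05 ± 0.11) and Spp1, osteopontin, which is also a cholangiocyte marker, from 246 to 63.3 CPM (-1.95 ± 0.29). LPD replicates 2 and 5 were lowest, at -1.86 and -1.98 relative to the SPD mean, against -0.89 to -0.49 in the other LPD livers. Of the 16 members, 3 (Lpl, Atp6v0d2 and Spp1) stood in another list too. Kupffer cell and macrophage markers fell in 6 of 20 cases, also adjusted over the list alone, Marco rose (0.53 ± 0.19, chosen after its value was seen) and 13 did not pass. Their median was -0.21 (adjusted p = 0.0293, and adjusted p = 0.631 with an estimated correlation), and -0.074 without LPD replicates 2 and 5. Folr2 (-0.49 ± 0.092), Cd14 (-0.87 ± 0.18) and Mpeg1 (-0.58 ± 0.14) fell, and LPD replicates 2 and 5 were lowest for this list too (-0.52 and -0.56).

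The Kupffer cell call was lost without LPD replicate 2 (adjusted p = 0.0615), LPD replicate 5 (0.0795) or SPD replicate 6 (0.0786), in alternatives reaching 0.219 without LPD replicates 2 and 5, and by exact permutation (adjusted p = 0.107). Folr2 missed the threshold with LPD replicate 1 counted as SPD (adjusted p = 0.0576). Stellate cell and fibroblast markers fell in 13 of 24 cases, also adjusted over the list alone, Ecm1 rose (0.39 ± 0.093, chosen after its value was seen) and 10 did not pass. Their median was -0.51 (adjusted p = 0.00187, and adjusted p = 0.608 with an estimated correlation). The collagens Col5a2 (-1.37 ± 0.25) and Col3a1 (-1.13 ± 0.27, 93.5 to 42.6 CPM) and the mural cell marker Rgs5 (-0.57 ± 0.12) fell. LPD replicates 2 and 5 were lowest for stellate markers as well, at -0.99 and -1.08, and without them the median was -0.32. LPD replicate 1, whose labels conflict, lay at -0.049, within the range of the SPD livers (-0.173 to 0.251). Its Col3a1 level, 79.0 CPM, lay within theirs too (67.3 to 112.8 CPM).

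Sinusoidal endothelial markers were not called (adjusted p = 0.103, median -0.11): 4 of 21 fell, Oit3 rose and 16 did not pass, with 4 fallen and 0 risen adjusted over the list alone. Cdh5 fell (-0.37 ± 0.057), with Flt4 (-0.41 ± 0.081), Kdr (-0.25 ± 0.054) and Stab1 (-0.19 ± 0.060), which like Oit3 (0.14 ± 0.048) were chosen after their values were seen. The endothelial list was called down without SPD replicate 6 (adjusted p = 0.0451) or LPD replicate 1 (0.0431), with LPD replicate 1 counted as SPD (0.0133), and passed fry (0.0325). Cholangiocyte markers were not called (adjusted p = 0.282, median -0.16), with Spp1, Prom1 and Pkhd1 (-0.29 ± 0.11, the last 2 chosen after their values were seen) fallen among 10, 2 adjusted over the list alone, and 7 not past. With LPD replicate 1 counted as SPD the cholangiocyte list was called down (adjusted p = 0.0369), whereas without LPD replicates 2 and 5 its median was positive, 0.066, and its mean was -0.17. Lymphocyte markers were not called (adjusted p = 0.944), with only Ighm (-1.98 ± 0.38) fallen among 10, also adjusted over the list alone. Their median was 0.088, the mean -0.13 and the test's direction down, and without LPD replicates 2 and 5 the median was 0.32 and the mean 0.13. Neutrophil markers were not called (adjusted p = 0.143, median -0.43), with Mmp9 (-1.27 ± 0.34) and S100a8 (-1.01 ± 0.38, chosen after its value was seen) fallen among 7, 1 adjusted over the list alone, and the list was called down with no low-count filter (adjusted p = 0.0387). In the SP1 and LP4 libraries alone Mmp9 did not pass (adjusted p = 0.183).

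Erythroid markers were called down (adjusted p = 0.0462, and adjusted p = 0.608 with an estimated correlation, median -1.05), although edgeR called 0 of the 6 members, also adjusted over the list alone. LPD replicate 4 lay at 0.792, above the SPD mean, and the other LPD livers at -2.13 to -1.54. The mean log2 fold change of the erythroid members was -0.90 with all livers and -0.30 without LPD replicates 2 and 5, where the median was -0.66. The erythroid call was lost in 14 alternatives (adjusted p 0.0524 to 0.127). Among these were the fits without SPD replicates 2 (0.0524), 3 (0.0681), 4 (0.0538) or 5 (0.0690) and without LPD replicates 1 (0.0757), 2 (0.0556), 3 (0.0906), 5 (0.0646) or 6 (0.0623). Adipocyte markers were not called (adjusted p = 0.220, median -0.49, and -0.20 without LPD replicates 2 and 5), with Lipe and Fabp4 (-1.12 ± 0.18) fallen and Car3 (1.31 ± 0.24) risen among 5, also adjusted over the list alone, the latter pair chosen after their values were seen. Of the exocrine pancreas markers only Cela1 could be tested, and it fell (-0.44 ± 0.11).

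Among the 8 largest rises that met the limits of the naming rule on level, overlap and gene type were those of Vmn2r3 (4.86 ± 0.48, 0.327 to 9.84 CPM), Pcp4l1 (3.42 ± 0.14, 2.06 to 22.0 CPM, adjusted p = 1.49e-09), Chac1, Fgf21, Igfbp2, Trib3 and Gadd45a. LPD replicate 4 was highest for Vmn2r3, a vomeronasal receptor gene, at 23.1 CPM. The 8 largest falls within the same limits were those of Chrna4, Akr1c18 (-3.98 ± 0.43), Lrtm2 (-3.94 ± 0.48), Scd2, Fabp5, Cyp21a1 (-3.38 ± 0.46), Pnpla3 and Elovl6. Chrna4, a nicotinic receptor subunit (ENSMUSG00000027577, chromosome 2, 181018380 to 181043546, minus strand), had 1304 counts over the SPD livers and 12 over the LPD livers (-6.74 ± 0.44, 10.4 to 0.0875 CPM). Genes near or antisense to these can share reads where counting ignores strand.

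Of the 22 lists called by camera, 20 also passed the exact two-sided permutation test of their mean, and mitochondrially encoded mRNAs and Kupffer cell markers did not. Like fry, the permutation test does not compare a list with other genes, and 39.9% of all tested genes were called. The largest adjusted p among the 20 was 0.0303, and 17 stood at 0.0056, which goes with the smallest p that 924 labelings allow, 0.00216. Lipid droplet, autophagy and lysosome, sinusoidal endothelial, neutrophil and adipocyte lists passed this test without being called by camera. By fry the lipid droplet (adjusted p = 0.0192), autophagy (0.00897) and adipocyte (0.000403) lists passed too. Where a list had 0 genes in a direction by edgeR, an unadjusted p under 0.05 gave 0 too, except for 1 fallen ER chaperone gene, 1 risen cholangiocyte marker and 2 fallen erythroid markers. DESeq2 and limma-voom gave 0 as well, except for 1 fallen ER chaperone gene with each and 5 fallen erythroid markers with limma-voom.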

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

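The test of mRNAs that start with an oligopyrimidine tract was chosen only after the rise of ribosomal protein mRNAs was seen, while the test of transcript length was chosen before. Values of named genes and of lists were checked in each group of 6 livers for a single liver far from the other 5, by Dixon's test. Of 302 groups checked 20 had such a liver (6.62%), and chance gives about 1 in 20.

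SPD replicate 6 stood apart most often. It was lowest for Cyp2c50, at 166 CPM against 199 to 217 in the other SPD livers, and for Cyp2c37, at 44.2 against 64.2 to 76.0. Its xenobiotic metabolism score was lowest too, -0.183 (log2, relative to the SPD mean) against -0.012 to 0.088. The same liver was highest for Folr2, at 18.3 CPM against 13.5 to 15.2, for interferon response genes, at 0.664 against -0.237 to 0.050, and for p53 and growth arrest genes, at 0.292 against -0.122 to 0.0036. SPD replicate 3 had the lowest Pnpla3 level, 1.78 CPM against 4.70 to 6.27, and the lowest glycolysis score, -0.180 against -0.016 to 0.081. It also had the highest Srebf1 level, 232.5 CPM against 130.6 to 156.7, and the highest Nr5a2 level, 47.4 CPM against 44.0 to 45.2.

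Among LPD livers, replicate 3 was highest for Gsta4, at 31.9 CPM against 21.1 to 23.4, and for Gsta2, at 28.7 against 14.4 to 18.1. Replicate 1 was highest for Apoc2, at 312.8 CPM against 242.5 to 259.1. Replicate 4 was highest for Acaca, at 221 CPM against 141 to 166, for Vmn2r3, at 23.1 against 3.61 to 9.85, and for erythroid markers, at 0.792 against -2.13 to -1.54. Replicate 2 was highest for Calr, at 845 CPM against 637 to 708, and for male-biased genes, at 0.444 against -0.274 to -0.093. Replicate 6 was lowest for Rps9, at 250.4 CPM against 281.7 to 298.0, and for ribosomal proteins as a list, at 0.146 against 0.280 to 0.331.

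Ribosomal protein mRNAs rose together in LPD livers, with a median of 0.27 over 57 genes. A bias toward short transcripts was tested with 464 other genes matched on length and expression (20 per gene, median length 837.5 bases against 820 for ribosomal protein genes and 2771.5 for all tested genes). Their median log2 fold change was -0.028 (bootstrap 95% range -0.053 to -0.014 over 2000 resamples), which argues against such a bias as the whole cause. Other mRNAs of the translation machinery that start with an oligopyrimidine tract had a median of 0.224, at the 99.4th percentile of 10000 random lists matched on expression (upper end of their central 95%, 0.181), and 16 of 22 rose while none fell by edgeR. The random lists were drawn gene by gene, so this percentile does not allow for correlation among these mRNAs or for spread between livers. Spliceosome mRNAs of a KEGG map rose too, so rises were not particular to the translation machinery. As a hypothesis, a change shared by mRNAs that start with such a tract may underlie the rise of ribosomal protein mRNAs. Whether the diet causes it was not tested apart from the library codes, which are nested in diet.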

How the results depend on the processing

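The alternative without LPD replicates 2 and 5 and the exact permutation test of list means were chosen only after the data were seen. The counts of genes higher and lower in LPD livers stayed within 1.5 times those reported in all but 2 alternatives: the SP1 and LP4 libraries alone (1827 and 1693) and the test beyond 1.5-fold (174 and 374), where fewer libraries and a stricter hypothesis are part of the construction. Elsewhere they ranged from 2265 higher and 2224 lower with LPD replicate 1 counted as SPD to 2830 and 2801 by DESeq2, and with 1 library left out from 2555 to 2803 higher and from 2391 to 2653 lower. No gene called in the comparison was called in the opposite direction in any alternative. Of the 2850 higher and 2646 lower genes, 2782 and 2635 were kept by DESeq2 and 1766 and 1626 in the SP1 and LP4 libraries alone. With the replicate number as a block 2668 and 2562 genes were called, and the number carried no sign of pairing, with correlations of -0.054 to 0.097 between livers of the same number. The count of called lists ranged from 19 to 24 with 1 library left out and fell from 22 to 0 with an estimated correlation, which allows for the correlation between the genes of a list. The difference between the mean correlations of LPD replicate 1 with its own and the other diet was 0.00282 with no low-count filter against 0.00947 as reported. Signs changed only for results not past the threshold, and the cause was not tested: male-biased genes (mean -0.0087 with upper quartile scaling, -0.059 with the replicate block, -0.14 without LPD replicates 2 and 5), the urea cycle (0.24 with no low-count filter, 0.029 with LPD replicate 1 counted as SPD), amino acid catabolism (-0.047 in the SP1 and LP4 libraries alone, -0.013 without LPD replicates 2 and 5), lymphocyte markers (0.13 without LPD replicates 2 and 5), Cps1 (-0.11) and Pck1 (-0.057) in the SP1 and LP4 libraries alone, and Srebf1 (0.00071) with limma-voom. Signs of lists are those of their means, and without LPD replicates 2 and 5 the median of cholangiocyte markers changed sign too (0.066 against -0.16), as did that of amino acid transporters (0.0085 against -0.069). With 1 library left out, values ranged from -0.063 to 0.016 for the urea cycle, -0.12 to 0.071 for Srebf1, -0.031 to 0.105 for Pck1, -0.14 to 0.044 for male-biased genes, -0.0046 to 0.045 for amino acid transporters and -0.021 to 0.23 for interferon genes. Over all alternatives named genes kept direction and side of the threshold in 2375 cases, lost the call in 7, gained it in 3 and changed sign in 7. For lists these numbers were 958, 57, 26 and 15. Low counts limit rare transcripts: 32001 genes had no count in any library.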

Other observations

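The tests that set macrophage markers against other markers, the position test of LPD replicate 1 and the test of KEGG maps with its example genes were chosen only after the results were seen, while the splits of the libraries were planned. KEGG maps, which were not among the fixed lists, showed further groups of mRNAs that moved. Ribosome biogenesis mRNAs rose in 41 of 70 cases, among them Wdr43 (0.58 ± 0.066), Mdn1 (0.62 ± 0.074) and Heatr1 (0.58 ± 0.073) (adjusted p = 1.1e-06, and 0.408 with an estimated correlation). Spliceosome mRNAs rose in 56 of 128 cases and fell in 5, with Prpf38b (0.61 ± 0.066) and Srsf4 (0.52 ± 0.056) as examples (adjusted p = 9.3e-06, and 0.408 with an estimated correlation). DNA replication mRNAs fell in 24 of 34 cases, among them Mcm4 (-1.21 ± 0.12) and Mcm3 (-1.06 ± 0.11) (adjusted p = 2.1e-05, and 0.540 with an estimated correlation). Lysosome mRNAs fell in 47 of 119 cases and rose in 12, and Gm2a fell (-0.90 ± 0.062) while Hyal1 rose (0.88 ± 0.079) (adjusted p = 0.00219, and 0.587 with an estimated correlation). Of 319 maps with 10 to 300 tested genes camera called 13 up and 55 down. With an estimated correlation camera called 0 maps, and 24 had an unadjusted p under 0.05.

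Of 100 splits of the 12 libraries into 6 and 6, only 1, the real one, gave as many higher genes (2850 against at most 1 in another split). Only 1, again the real one, gave as many lower genes (2646 against at most 1). This argues against a random labeling as the source of either count, though 1 in 100 is the smallest share these splits can give. Every other split mixes the diets within its groups, which adds spread there, so the margin is not one over livers without a diet effect. Nor can the splits tell the diet from the library codes, which are nested in it. For lists called by camera with the preset correlation, 20 of the 100 splits gave as many (22 in the real split, up to 27 in another), so chance cannot be excluded for the number of lists called.

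Lipid-associated macrophage markers fell by more than sinusoidal endothelial markers and than Kupffer cell and macrophage markers, the only lists they were tested against. By the mean log2 CPM of its members, the stellate list moved by -0.573 and the erythroid list by -1.42. For the erythroid list LPD replicate 4 lay above the SPD mean (0.792). The neutrophil list moved by -0.555, the cholangiocyte list by -0.342 and the lymphocyte list by -0.109. None of these was compared with them by a test. If all cells other than hepatocytes had been fewer alike, endothelial markers would have fallen alike, but the mean macrophage score fell by 0.974 more on the log2 scale (-1.09 against -0.114, exact permutation p = 0.00216, the smallest possible), and by 0.583 more without LPD replicates 2 and 5. Against Kupffer cell and macrophage markers, which moved by -0.243, the difference was -0.845 (exact permutation p = 0.00216, the smallest possible), and -0.575 without LPD replicates 2 and 5. This argues against a lower share of all such cells alike and against fewer macrophages of every kind as the whole cause. In the first test endothelial markers stood alone for the other cells. LPD replicates 2 and 5 were the lowest LPD livers for endothelial, neutrophil, lymphocyte and cholangiocyte markers as well. They were the highest for hepatocyte identity genes (0.316 and 0.321). A lower share of cells other than hepatocytes in these livers, as a part of the fall, stays open. A smaller or less lipid-loaded macrophage subset on the low protein diet is a hypothesis that may account for the fall, but lower expression in other cells stays open, since Anxa5 (485 to 196 CPM) and Spp1 (246 to 63.3 CPM), the most abundant named markers, are not confined to macrophages.

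LPD replicate 1 has 2 labels that name the standard protein content. On an axis from the mean of the SPD livers (0) to that of the other LPD livers (1), over all tested genes, it lay at 0.713, outside the range of the SPD livers (0.011 to 0.147) and below that of the other LPD livers (0.810 to 1.23). An earlier test took the genes called without this library that were also among the 13768 tested, 5422 in all: 74.1% lay on the LPD side in it, against 83.3% to 94.4% in the other 5 LPD livers, which missed the bound set for that test, over 90%, and the position test replaced it after that was seen. Those 5 livers had helped to call these genes and LPD replicate 1 had not, so their higher share was in part built in. The position argues against an origin from an SPD liver, and the earlier test decided nothing by its own bound. Scd1 (6023 CPM), Fasn (247 CPM), Acaca (158 CPM) and Acly (171 CPM) of this library lay within the other LPD livers. The lowest SPD levels were 32314, 1005, 398 and 439 CPM, which for these genes argues against a large share of SPD RNA. Scd2 (25.0 against 10.9 to 23.0 CPM) and Fabp5 (10.9 against 2.96 to 9.99 CPM) lay above the other LPD livers. A weaker response could explain the place of this library short of the other LPD livers and stays open, as does a small share of SPD RNA.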
